A study of Gallus gallus with 6 samples.

How the data were processed

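The samples were ileum, the last part of the small intestine, of male Taiping chickens aged 2 months. Per the labels, 3 libraries came from control birds on a corn and soybean diet (CT, 0 mL of probiotic per litre) and 3 from birds whose drinking water held 2 mL of probiotic per litre (MP). Per the labels' protocols, total RNA was extracted with TRIzol, and about 3 µg per sample went into libraries made with a kit that the labels describe as one for small RNA. The values nevertheless covered messenger RNA genes of all lengths, and no size selection is given in the sources used here. The submitters' processing notes name fastp 0.18.0, Bowtie2, HISAT2, StringTie 1.3.1 and DESeq2, with no role or order. The genome build is not given in the sources used here, so no coordinates are printed.

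The table holds 17623 genes, of which 16568 carry Ensembl chicken identifiers and 1055 are assembled loci. The authors deposited, per the file headers, an FPKM value (fragments scaled to transcript length and sequencing depth) for each gene and each group, not for each library. The authors also deposited an estimated count per gene and group, which was not scaled to depth; these summed to 17150865 per library in CT and 15928865 in MP. In both groups 100.0% of the FPKM values and 100.0% of the counts end in 0, 3 or 7 at the third decimal, as means of 3 values with 2 decimals do. Of the mean counts, 89.9% in CT and 90.2% in MP gave a whole number when multiplied by 3 (within 0.002), so some counts per library were estimates and not whole. Each value is therefore printed as the authors' mean of 3 libraries. No standard deviation can be derived from it, and no difference below has a replicate check. The table also has 4 columns of values that belong to no sample of this series; they were not used.

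The design fixed before the data were examined had a count test across the 6 libraries and a set test of gene lists. Neither could be run on group means, so no p-value is given. The fallback fixed with that design, which covers only the naming of genes, was used. Differences are on the log2(FPKM + 1) scale, MP minus CT, which understates the difference of genes with low values. Genes were counted at 2-fold and at 1.5-fold on that scale among genes with FPKM of at least 5 in either group; these thresholds were set after the table proved to hold group means only. The genes named are the 10 with a symbol that lay highest and the 10 that lay lowest in MP at that minimum, the 3 genes with the largest mean count, and 6 tissue markers (MUC2, PIGR, FABP6, CD3E, MYH11 and HBBA). From each gene list up to 4 members with the largest difference at that minimum could be named, a rule also set once the table was seen. Any other gene named was chosen after its values were seen, except GATA4, whose test was written before its value was looked up. The values of some single genes are not reported here. Symbols are those of the table (12776 genes). Of 13969 genes with an NCBI gene number, 13650 were found in the RefSeq gene table of assembly GRCg7b, which was used for names only.

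For named genes the mean counts were multiplied by 3 and rounded, and the MP to CT ratio was divided by the depth ratio of 0.929. Its exact 95% interval (Clopper-Pearson, conditional on the sum of both counts) covers counting error only: reads from PCR without molecular identifiers are not independent molecules, and variation between birds is not in it.

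Gene lists for pathways and cell types (39 lists) were fixed before the data were examined. Of these, 38 had at least 5 members with FPKM of at least 1 in either group. The median log2 difference of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This placement was not part of the design fixed beforehand. A list is called above or below when its median left the central 95% of the random medians, between the 2.5 and 97.5 percentiles. This describes these libraries and is no test of the treatment, since genes of a list vary together between animals. A second set of random lists was matched in 10 bins of mean expression and in 5 bins of the ratio of count to FPKM, which follows transcript length. The pathway names in the table's own KEGG annotation were treated alike where at least 10 genes were measured.

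The steps were tested on simulated data for MP against CT. Among 9913 genes, the 2-fold threshold recovered 0.00% of 50 genes simulated at 1.50-fold, 94.00% of 50 at 2.50-fold, and 100.00% of 50 each at 4.00-fold and 8.00-fold. It took 0.00% of the 9713 unchanged genes. The simulated counts held counting error only and no variation between birds, so 0.00% is not the false positive rate for the real groups. Of 200 random lists of 20 genes (12828 genes), 6.00% fell outside the band on either side with no shift. With an upward shift of 0.15 in log2, 69.50% lay above the band, and with 0.30, 100.00%. Genes drawn at random do not vary together as those of a pathway can, so these rates check the calculation and do not carry over to the real lists.

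Alternatives planned beforehand and run were a pseudocount of 0.1, median-of-ratios and upper-quartile scaling, library totals (CPM), the 20 largest genes left out of the totals, no filter on low values, and lists without shared members. Added after seeing the data were equal FPKM totals, assembled loci left out, other minimum values (FPKM of 1 for genes and 5 for lists) and length-matched random lists. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for the plots.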

Results

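Gene expression was measured by RNA sequencing in the ileum of 6 male Taiping chickens, 3 without supplement (CT) and 3 given a probiotic in the drinking water (MP). The comparison asks how the ileal transcriptome of supplemented birds differs from that of birds on the basal diet. The authors' mean counts summed to 17150865 per library in CT and 15928865 in MP. The labels give neither the time of day of sampling nor the position along the ileum. FPKM reached 1 for 12642 genes in CT and 12596 in MP. The 20 largest genes took 11.6% of the counts in CT and 12.4% in MP. The largest mean counts belonged to COX1 of mitochondrial DNA (FPKM 11371 in CT and 12539 in MP), to the MHC class II invariant chain Ii (5958 and 5151) and to the actin gene ACTG1 (3482 and 4616). Every value is the authors' mean of 3 libraries, so no difference could be set against the spread between birds.

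In the MP mean, genes for cholesterol synthesis were higher as a group, and so were some genes of sugar and fat uptake and of mucosal defence, while others on the same lists were lower. Of 20 measured genes of cholesterol synthesis, 19 were higher, with a list median of 0.53 in log2. The glucose transporter gene SLC2A2 went from FPKM 0.50 in CT to 10.2 in MP, and the chemokine gene CCL20 from 10.99 to 48.1. Genes of smooth muscle, connective tissue, fat cells and the cell cycle were lower in the MP mean. All 26 smooth muscle genes and all 41 cell cycle genes lay below CT, with list medians of -0.37 and -0.35.

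Among 9913 genes with FPKM of at least 5 in either group, 79 were at least 2-fold higher and 25 at least 2-fold lower in MP on the log2(FPKM + 1) scale. The counting interval excluded equality for all 104. Counting error alone, in 20 simulated draws, gave a mean of 0.0 genes at 2-fold and 0.1 at 1.5-fold. The 104 genes were picked for their difference, and neither check holds variation between birds. They show only that counting error is too small to account for these differences, and do not test the treatment. At 1.5-fold, 254 genes were higher and 152 lower, so that 62.6% lay on the higher side. That share depended on the scaling. It was 76.8% with median-of-ratios scaling (334 higher and 101 lower), 71.5% with upper-quartile scaling and 47.0% with equal FPKM totals (197 and 222). With library totals it was 51.4% (276 and 261), but this setting also replaced FPKM by CPM and took in 11219 genes. It shifted the median gene by only -0.006, so its lower share cannot be put down to scaling alone. With the FPKM values as deposited, the median gene lay at -0.07, with quartiles at -0.20 and 0.10.

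SLC2A2 (ENSGALG00000009306), which carries glucose and fructose out of the enterocyte, had the largest difference among genes with a symbol, 2.90 in log2. Its depth-scaled count ratio was 20.3, with a counting interval of 15.6 to 27.0. ST3GAL4 (ENSGALG00000029747), a sialyltransferase, had FPKM 7.50 in CT and 55.0 in MP, a count ratio of 7.19 (6.60 to 7.84). AVD, the biotin-binding protein avidin, went from 34.5 to 181, a count ratio of 5.25 (4.96 to 5.56). The goose-type lysozyme gene LYG2 had FPKM 4.40 in CT and 21.9 in MP (2.08 in log2), and the fibrinogen gamma chain gene FGG had 2.19 and 11.2 (1.94). ENPP7, the alkaline sphingomyelinase of the intestine, went from 27.7 to 106 (1.90), and GIP, a hormone of the upper intestine, from 6.12 to 22.5 (1.72). IYD, an iodotyrosine deiodinase, was at 1.32 and 6.76 (1.74), and the chemokine gene IL8, described as interleukin 8-like 2, at 1.22 and 6.41 (1.74).

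The lowest gene with a symbol was GAL3ST2, a sulfotransferase acting on galactose, with FPKM 11.6 in CT and 3.19 in MP (-1.59 in log2). SPINK9, an assembled locus described as a Kazal-type protease inhibitor, went from 243 to 94.8 (-1.35). THRSP, a regulator of fatty acid synthesis, had 71.3 and 28.9 (-1.27). GTSF1 was at 24.4 and 9.78 (-1.24), and the activin receptor gene ACVR1C at 6.14 and 2.36 (-1.09). Structural genes in this set were TMSB15B (70.7 and 33.6, -1.05), the striated muscle actin gene ACTA1 (36.96 and 17.4, -1.04) and the hemidesmosome collagen gene COL17A1 (23.4 and 10.9, -1.04). The somatostatin receptor gene SSTR2 (6.78 and 2.83) and the kynureninase gene KYNU (8.49 and 3.68) both lay at -1.02.

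**Figure D1:**
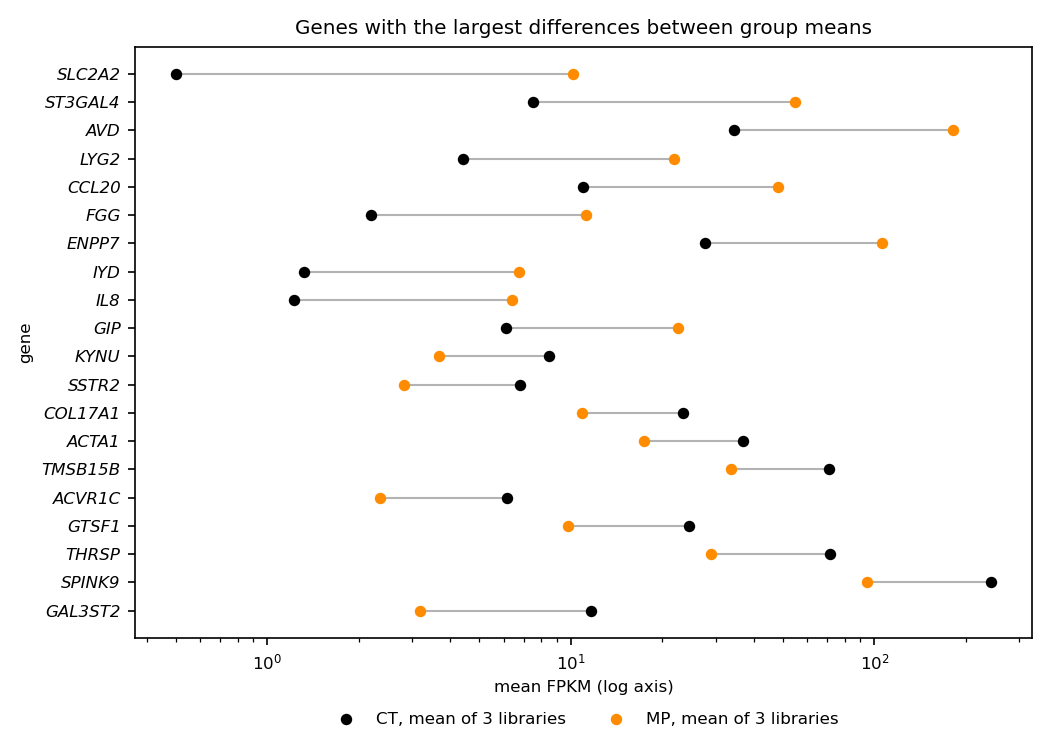
Authors' mean FPKM on a log axis for the 10 genes with a symbol that lay highest and the 10 that lay lowest in MP; black points are CT and orange points MP, each a mean of 3 libraries with no error available. SLC2A2 spans the widest interval, from 0.50 to 10.2.

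Of the 38 gene lists with enough measured members, 9 had a median above and 9 below the central 95% of 10000 random lists matched on expression. Lists of genes that vary independently would put 1.9 outside. Genes of a list vary together between birds and some lists share members, so more can leave the band without any effect of the treatment. The largest shift that any scaling gave to the median of all genes was 0.07 in log2. The other 20 lists lay inside the band.

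**Figure D2:**
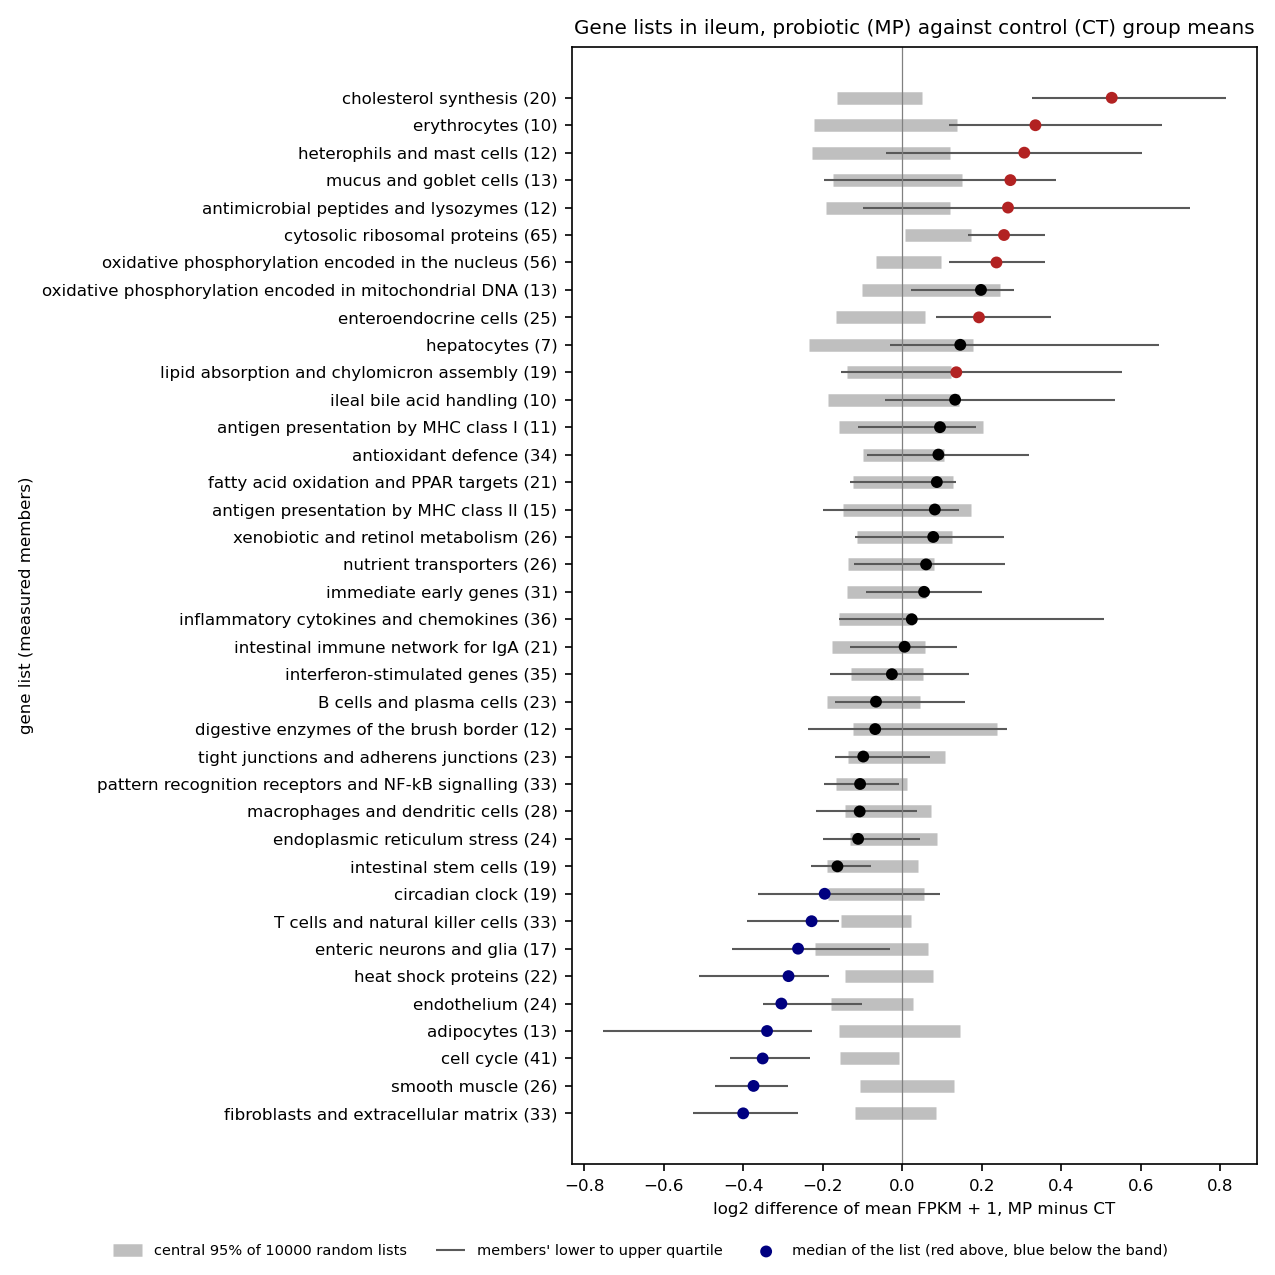
Median log2 difference of each gene list (points), lower to upper quartile of its members (thin lines) and the central 95% of 10000 random lists matched on expression (grey bars), with the number of measured members in parentheses. Cholesterol synthesis lies farthest above at 0.53, and fibroblasts and extracellular matrix farthest below at -0.40.

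Cholesterol synthesis had the highest median of all lists, and 9 of its 20 genes were at least 1.5-fold higher in MP and 0 lower. FDFT1, which makes squalene, went from FPKM 20.3 to 43.7, MSMO1 from 46.7 to 95.4, SQLE from 6.31 to 12.2 and LSS, which closes the sterol ring system, from 23.7 to 43.5. The same 19 to 1 split was found under each of the 4 other scalings. Lipid absorption and chylomicron assembly lay above the band by a small margin (12 of 19 genes higher, median 0.14, percentile 98.2). Its 1.5-fold members included the apolipoprotein genes APOA4 (41.2 in CT and 111 in MP) and APOA1 (806 and 1573) and the cholesterol carrier gene Npc1l1. With random lists matched on length the percentile of this list was 97.0, inside the band.

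Ileal bile acid handling lay inside the band (7 of 10 higher, median 0.13, percentile 96.7), and its members differed in direction. The export transporter genes SLC51B (25.8 in CT and 68.5 in MP) and SLC51A (140.0 and 219) and the hormone gene FGF19 (3.15 and 7.53) were higher. FABP6, the bile acid binding protein of the ileum, was lower at 4081 and 2669, with a count ratio of 0.656 (0.652 to 0.660). Nutrient transporters (26 genes, median 0.06) held SLC2A2 but also the peptide transporter gene SLC15A1 (357 in CT and 215 in MP) and the fructose transporter gene SLC2A5 (-0.74), both lower. With random lists matched on length, bile acid handling (percentile 98.2) and nutrient transporters (99.6) lay above the band. Digestive enzymes of the brush border (12 genes, median -0.07) included lactase, LCT, at 3.79 and 10.6, and the metalloprotease gene MEP1B at 201 and 125. GATA4, a transcription factor of the duodenum and jejunum that lies outside the naming rule, had FPKM 0.423 in CT and 2.31 in MP, a count ratio of 5.72 (4.67 to 7.06).

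**Figure D3:**
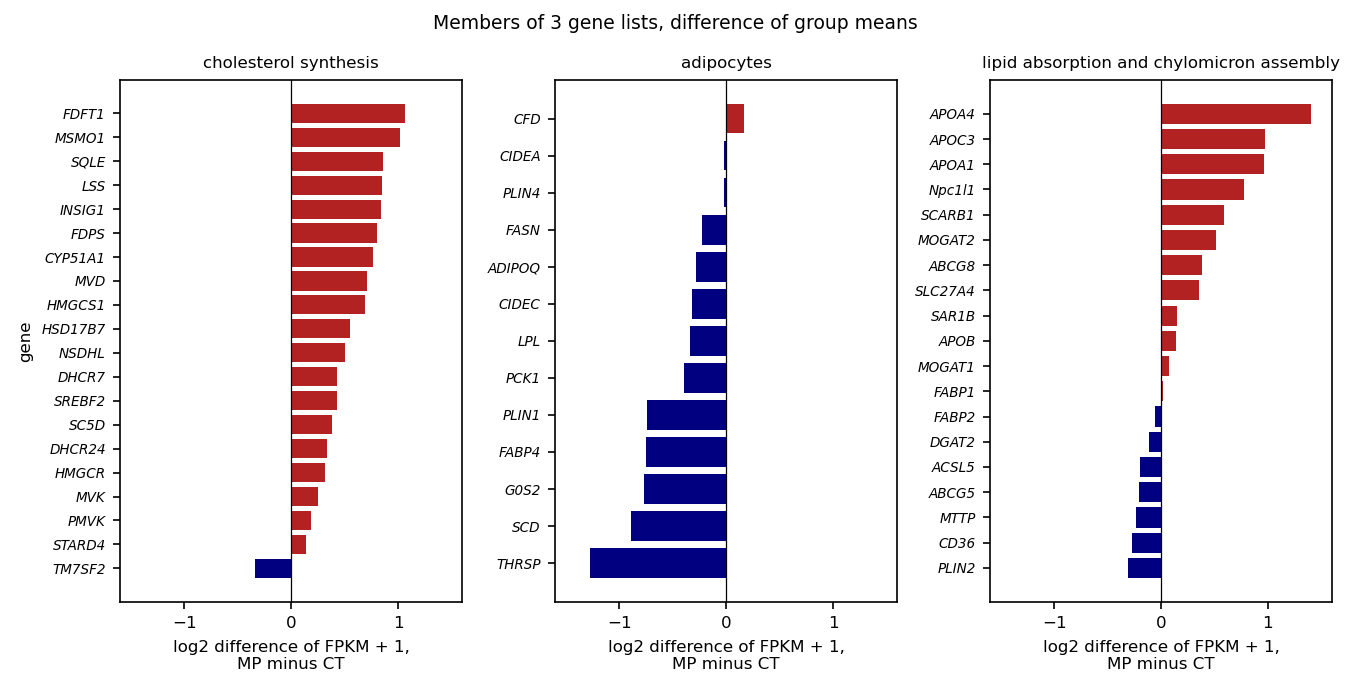
Log2 difference of FPKM + 1 (MP minus CT) for each measured member of 3 gene lists; bars start at 0, red is higher and blue lower in MP, and no error is available. Cholesterol synthesis has 19 of 20 bars on the higher side, lipid absorption 12 of 19 and adipocytes 1 of 13.

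Genes of energy production and translation were higher by small steps. Nuclear genes of oxidative phosphorylation were higher for 51 of 56 (median 0.24), and cytosolic ribosomal protein genes for 64 of 65 (median 0.26). Few members reached 1.5-fold, 1 and 2 genes. These transcripts are short, and short genes as a class lay higher in MP: the median was 0.12 in the tenth of genes with the lowest count per FPKM and -0.15 in the tenth with the highest. Against length-matched random lists the percentiles were 99.9 and 99.8, still above the band. The 13 protein genes of mitochondrial DNA lay inside the band (median 0.20). Fatty acid oxidation (21 genes, 0.09), antioxidant defence (34 genes, 0.09) and xenobiotic and retinol metabolism (26 genes, 0.08) also lay inside, the first of them above the band with length-matched lists (percentile 98.1). They held the glutathione transferase gene GSTT1 (9.01 in CT and 27.7 in MP) and the retinol carrier gene RBP2 (134 and 355).

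Among genes of mucosal defence, antimicrobial peptides and lysozymes had 7 of 12 members higher (median 0.27), and 5 of 10 with library totals. Besides LYG2, the lysozyme gene LYGL went from 17.7 to 39.7 and the peptide gene LEAP2 from 18.1 to 35.3, while RNASE6 was lower, at 47.9 and 27.7. Heterophils and mast cells had 8 of 12 higher (median 0.31). Each shares 5 members with other lists, and without those members their medians turned to -0.05 and -0.01, inside the band. Mucus and goblet cells had 8 of 13 higher (median 0.27), but came inside the band without a filter on low values (0.05) and without shared members (0.15). The secreted goblet cell gene CLCA1 went from 887 to 1424, whereas the main gel-forming mucin, Muc2, was lower in each of its assembled loci, at 3033 and 1916 in one and 523 and 354 in the other. Enteroendocrine cells had 20 of 25 genes higher (median 0.19), among them GIP, motilin (MLN, 38.0 in CT and 61.5 in MP) and peptide YY (PYY, 7.23 and 11.4).

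Inflammatory cytokines and chemokines lay inside the band at its upper edge (19 of 36 higher, median 0.02, percentile 97.3), and above it in 7 alternatives, among them median-of-ratios scaling (25 of 36 higher, median 0.10, percentile 98.3). With equal FPKM totals 17 of 36 were higher (median -0.035), and with length-matched random lists the percentile was 88.6. Of the 36 genes, 8 were at least 1.5-fold higher and 1 lower. CCL20, which draws lymphocytes and dendritic cells, had a log2 difference of 2.03 and IL8 1.74, and SOCS3, a brake on cytokine signalling, went from 32.7 to 67.0. The lymphoid chemokine gene CCL21 was lower, at 106 and 54.5. IL17A, chosen after its values were seen, had FPKM 0.167 and 1.63, a count ratio of 9.15 with a wide counting interval of 4.39 to 22.1. Interferon-stimulated genes (35 genes, median -0.03), pattern recognition receptors and NF-kB signalling (33, -0.11), and MHC class I (11, 0.09) and class II (15, 0.08) lay inside the band. The IgA network did so too (21 genes, 0.01), although JCHAIN, which joins IgA subunits, went from 687 to 1298. PIGR, which carries IgA across the epithelium, had a count ratio of 1.10 (1.09 to 1.11).

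T cell and natural killer cell genes were lower for 32 of 33 (median -0.23), and for 28 of 33 with median-of-ratios scaling. CD4 went from 15.3 to 9.87, TRAT1 from 16.2 to 10.4, EOMES from 6.10 to 3.61 and CD3E from 246 to 216. Genes of B cells and plasma cells (23 genes, -0.07) and of macrophages and dendritic cells (28, -0.11) lay inside the band. Red cell genes were higher for 8 of 10 (median 0.34), with the globin genes HBBA at 22.6 and 48.6 and HBA1 at 37.04 and 64.0. Markers of muscle and vessels, which a piece of ileum can hold in varying amounts, were lower beside these lists.

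Fibroblast and extracellular matrix genes were lower in MP for 32 of 33 (median -0.40). POSTN went from 17.5 to 9.10, and vimentin (VIM), tenascin (TNC) and fibronectin (FN1) lay at -0.71, -0.71 and -0.66. All 26 smooth muscle genes were lower, 24 of them with median-of-ratios scaling; CNN1 was at 227 and 135, ACTG2 at 1336 and 816, and MYH11 at 305 and 232. Endothelial genes were lower for 23 of 24 (median -0.30), and genes of enteric neurons and glia for 16 of 17 (median -0.26), the latter for 10 of 17 with median-of-ratios scaling. The neuronal list came inside the band with library totals (-0.20) and without a filter on low values (-0.10). Adipocyte genes were lower for 12 of 13 (median -0.34), 5 of them by at least 1.5-fold, including THRSP, SCD (6.99 and 3.31), FABP4 (161 and 95.3) and G0S2 (33.3 and 19.2). Of the liver list, 7 genes were measured (median 0.15, inside the band), and of the pancreatic list 1, too few to place.

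All 41 cell cycle genes were lower in MP under each scaling, by a median of -0.35, with 2 past 1.5-fold: RRM2, which makes deoxynucleotides, went from 24.2 to 14.3 and the proliferation marker MKI67 from 16.5 to 10.6. The stem cell list lay inside the band (16 of 19 lower, median -0.16), with LGR5 at 13.0 and 7.36. Heat shock proteins were lower for 20 of 22 (median -0.29), among them HSP90AA1 (710 in CT and 435 in MP), HSPH1 (30.6 and 17.5) and HSPB1 (229 and 140). CHAC1, a glutathione-degrading enzyme on that list, was higher at 5.25 and 12.6. Endoplasmic reticulum stress (24 genes, -0.11), immediate early genes (31, 0.05) and tight and adherens junctions (23, -0.10) lay inside the band. CLDN2, a pore-forming claudin, went from 56.4 to 91.8.

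The circadian clock list was lower for 13 of 19 genes (median -0.20, percentile 1.83), but its members went both ways. NPAS2, a partner of the clock activator, went from 6.64 to 17.8. The repressor gene NR1D2 went from 53.2 to 33.3 and PER2 from 33.9 to 23.6. With a minimum FPKM of 5 the median of this list was -0.02, inside the band.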

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

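The scaling to equal FPKM totals, the omission of assembled loci, the other minimum values and the length-matched random lists were chosen after seeing the data. No paired analysis was possible because the columns carry group means without replicate numbers. For that reason leaving out libraries, the planned count tests, DESeq2, limma-voom, limma-trend, camera, fry, TMM factors and filters across libraries were not run. Among the recomputed list medians, 383 kept their place inside, above or below the band. Genes at least 2-fold lower numbered 16 with median-of-ratios scaling and 41 both without a filter and at a minimum FPKM of 1. At 1.5-fold, 385 genes were higher without a filter. Genes lower at 1.5-fold numbered 101 with median-of-ratios scaling, 261 with library totals, 268 without a filter and 253 at a minimum FPKM of 1.

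Lipid absorption came inside the band without assembled loci (0.105), without shared members (0.105) and with length-matched lists (0.136, percentile 97.0). Mucus and goblet cells did so without a filter (0.048) and without shared members (0.151). Antimicrobial peptides were inside with library totals (0.003), equal FPKM totals (0.013) and a minimum FPKM of 5 (0.072). Without shared members their median changed sign (-0.047) and lay inside the band, not below it. Heterophils and mast cells were inside with library totals (0.085), no filter (0.008) and a minimum FPKM of 5 (0.153). Without shared members their median also changed sign (-0.014) and lay inside the band. Enteric neurons and glia came inside with library totals (-0.197) and no filter (-0.099), and the circadian clock at a minimum FPKM of 5 (-0.019). Fewer members enter without shared genes or at a higher minimum; otherwise the cause was not tested. Another 19 medians of lists inside the band left it, 7 of them for inflammatory cytokines, which then lay above. Of the recomputed differences of the 20 named genes 164 moved by less than the counting error and 15 by more; 0 reversed. SLC2A2, at FPKM 0.50 in CT, lay at 4.10 with a pseudocount of 0.1 and 3.49 with library totals, against 2.90.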

Other observations

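The GATA4 test and the gene length test were set before their results were seen; all other tests in this part were chosen afterwards, and the lists of proximal, distal, epithelial and clock genes were drawn up from general knowledge after the values had been seen.

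A few genes without a symbol in the table also differed widely. A gene described as beta-microseminoprotein (MSMB) went from FPKM 0.81 in CT to 15.8 in MP, a count ratio of 19.2 (counting interval 13.4 to 28.5). ASAH2, the ceramidase that acts after ENPP7 in the digestion of sphingomyelin, went from 3.78 to 17.7, a ratio of 4.72 (4.24 to 5.26). In the other direction the undescribed gene ENSGALG00000047627 went from 46.1 to 2.89, and ENSGALG00000039205, described as similar to a chaperonin subunit, from 8.96 to 0.027, a ratio of 0.0030 (0.00036 to 0.011). Extremes of this kind can rest on 1 bird or on a variant that affects mapping, which group means cannot show.

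Of 149 pathway groups named in the table, 26 lay above and 29 below their random bands. Groups can share genes, and genes of a group vary together, so these counts test nothing. With random lists matched on length, some groups came inside, such as endocytosis (percentile 4.36), tight junction (4.14) and pyrimidine metabolism (96.9). Others left the band, such as fatty acid metabolism (99.1). The groups named below stayed outside. Steroid biosynthesis had the highest median (14 genes, 0.53). Fructose and mannose metabolism was higher for 19 of 29 genes (0.20), with ketohexokinase (KHK) at 10.7 in CT and 21.5 in MP. ECM-receptor interaction was lower for 47 of 56 genes (-0.24), cell adhesion molecules for 64 of 81 (-0.22) and focal adhesion for 131 of 156 (-0.20).

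Of 31 genes used mostly in the duodenum and jejunum, a list that took in genes already seen to be high and so describes the pattern without testing it, 23 were higher, 16 of them at least 1.5-fold, with a median of 0.68, while 8 were lower, of which SLC15A1 (-0.73) and SLC2A5 (-0.74) passed 1.5-fold. Liver RNA is argued against, since ALB stood at FPKM 0.170 in MP against 11.2 for FGG. For a larger share of epithelium, the 22 general epithelial genes had a median of 0.119 and an upper quartile of 0.164. The upper quartile of the brush border list fixed beforehand was 0.26. A common rise of that size would not alone give 2.90 for SLC2A2, 1.90 for ENPP7 or 1.72 for GIP. The fixed rule named these genes for being among the largest rises. The comparison therefore covers them alone, and a larger share stays undecided for the proximal genes as a set. A candidate explanation is that the MP pieces came from nearer the proximal end. GATA4, chosen as a gene that the ileum is thought to switch off, had a count ratio of 5.72 (4.67 to 7.06, 112 counts in CT and 595 in MP). Its means were low, at FPKM 0.423 in CT and 2.31 in MP. Group means cannot show whether all MP birds share the difference. The 21 genes of the distal intestine had a median of -0.019, inside the band of -0.147 to 0.115. A proximal position predicted a median below that band, which was not met. The median lay just above that of the random lists (-0.028, percentile 55.6), the outcome set for no such position. So small a margin does not rule the position out, and members went both ways. Of the 21 genes, 10 were higher and 11 lower. Muc2 (-0.66), FABP6 (-0.61), NR1H4 (-0.47) and HOXA10 (-0.36) were lowest. SLC51B (1.38), FGF19 (1.04), AMN (0.70), SLC51A (0.64) and PYY (0.59) were highest. A response of the ileum to the probiotic stays open and untested, as the labels give no position along the gut.

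Muscle, connective tissue, endothelial and neuronal genes were lower in MP together, with the highest percentile of the 4 lists at 0.37, that of the neurons, which came inside the band with library totals (-0.197) and without a filter (-0.099). Gene length bias is argued against as the whole cause for muscle and connective tissue: with length-matched random lists the higher of their percentiles was 0.00. Less muscle coat and connective tissue in the MP pieces, lower expression within those cells and an effect of the probiotic on the gut wall all stay open, because the low percentiles are the pattern itself and support none of them over the others.

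Clock genes lay on both sides: PER3 (4.97 in CT and 2.49 in MP) and NR1D1 (4.65 and 2.59) were lower, as was CLOCK (20.3 and 17.9), while ARNTL (9.57 and 13.2), NPAS2 (6.64 and 17.8) and the repressor gene CRY1 (54.3 and 59.3) were higher. A split into 6 genes around the activators and 9 repressors and D-box factors gave medians 0.751 apart, with 0.344 for the former. That split was drawn up after the values had been seen, left out CRY1 and put NFIL3, a repressor of D-box genes, with the activators, so these values decide nothing. Sampling at a different phase of the clock, another share of muscle and connective tissue and an effect of the probiotic on the clock all stay open, and the time of day of sampling is not in the labels.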
